A study of Mus musculus with 9 samples.

How the data were processed

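Gene expression was measured by RNA-seq of poly(A) RNA in 9 libraries of cells sorted from mouse neural tube organoids, in 3 groups of 3 biological replicates (GFP- and GFP+ under RA, GFP+ under SAG). Cells were grown, sorted with a GFP filter set, and their RNA made into libraries with a directional (stranded) kit, per the labels' protocols. The deposited table holds raw counts per Ensembl mouse gene ID, with 1 column per library. Its values show no normalization: they are whole numbers, and the column totals differ between libraries. Per the submitters' processing notes the tools were Trim Galore 0.5.0, Bowtie2 2.3.4.1 and featureCounts from Subread 1.6.2, on the genome build GRCm38. The strand setting of the counting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap another gene, or have near-identical copies such as Hspa1a and Hspa1b or the Rhox family, are uncertain. The sources give the RA dose as 250 nM in the series text and as 250 µM in the treatment protocol, and which holds was not settled. SAG appears in the sample titles alone, and the treatment protocol speaks of medium with or without RA. The SAG dose is unknown and SAG medium is taken to lack RA. A GFP- population from SAG medium is not listed, so sort and medium can be told apart only in comparisons that share one of them.

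The table has 54532 genes, of which 24114 have 0 counts in all libraries. Of these 54532, 54409 were given a symbol, from the annotation of the same build, and coordinates are 1-based. Total counts per library run from 25281871 to 29763765. Of all counts, 0.002% came from the mitochondrial genome and 98.65 to 98.88% from protein-coding genes. CPM are counts scaled by the library's total over the tested genes times its TMM scaling factor. For a gene with 0 counts in a group, fold changes are given as "at least", against 3 counts over the group (0.039 CPM for the SAG libraries, 0.0371 CPM for the GFP- libraries). For 1 to 3 counts the ratio of counts is given with an exact 95% interval. These floors and intervals cover counting error only.

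Genes were tested with edgeR 4.0.16 (R 4.3.3) in 1 fit of all 9 libraries with a mean per group: TMM scaling, genes kept by filterByExpr with a minimum count of 10 (16772 genes), quasi-likelihood tests, and Benjamini-Hochberg adjusted p over all tested genes within a comparison. A gene is called higher or lower when this adjusted p is under 0.05, and "rose", "fell", "higher" and "lower" are used of called genes. The SE of a log2 fold change is its size divided by the square root of the test's F value. Scaling factors ran from 0.972 to 1.029, and the biological coefficient of variation was 0.226. The median log2 fold change over all genes was -0.018, -0.017 and -0.009 in the 3 comparisons. Log2 CPM for the principal components and correlations used a prior count of 2. Counts of calls were also checked for dependence on single libraries.

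The 26 gene lists (287 genes in all) were written from general knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes, except where the text says otherwise. For each list the number of members called is given over all genes and adjusted over the list alone, and limma 3.58.1 camera compares the list with all other tested genes at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists of a comparison. A camera call means that the list ranks above or below other genes in these libraries. Where it was lost with a correlation estimated from the data, that adjusted p is given beside it, and it was the highest of all alternatives for each such list. One list member, Ddit3, is not in the table.

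Genes are named by a fixed rule. For the first 2 comparisons these are Foxa2, Shh, Nog and Olig2, the 5 highest and 5 lowest log2 fold changes among called genes whose groups do not overlap and that reach 5 CPM in the higher group, and in each list the 2 called members with the smallest adjusted p (or the member with the smallest p). For the comparison of GFP+ under SAG with GFP- under RA they are Foxa2 and the 5 highest and lowest. Groups of 3 and 3 libraries fail to overlap for 10% of genes by chance. All genes named by the rule had groups that did not overlap (3 of 3 libraries on the same side), except Olig2 in both of the first 2 comparisons and Slc2a1 under RA. Some genes that the rule picks are not named in the text, while counts of lists and of alternatives include them. Other genes, among them list members named to show what made up a count, were chosen after their values were seen.

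Both fits with and without the replicate number as a block were planned. Deviations from the group means correlated between same-numbered GFP- and GFP+ libraries under RA for each number (r = 0.273, 0.307 and 0.347, across genes), so the numbers pair the RA libraries, while the labels call them biological replicates and say no more. Between SAG and RA libraries the correlations for numbers 1 to 3 were 0.111, -0.082 and 0.182 (GFP+) and 0.175, -0.022 and 0.242 (GFP-). For number 2 they were below 0, so pairing by number was not shown there and stays open. The alternatives were DESeq2-style size factors (RLE), the DESeq2 1.42.0 Wald test, no filter on low counts, only the 6 libraries compared, the replicate block, a test against a fold change of 2, fry and estimated correlations for the lists, and leaving out each library in turn. A replicate block in the 6 RA libraries was added after seeing the data.

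The tests were run first on simulated data with the real genes' means, 200 changed genes and 3 libraries per group. edgeR found 92%, 94% and 96% of 4-fold changes, 56%, 52% and 52% of 2-fold changes and 10%, 20% and 14% of 1.5-fold changes in the 3 comparisons (16408, 16400 and 16383 genes), and 2.3%, 5% and 3.7% of its calls were unchanged genes. DESeq2 (16772 genes) had 24%, 22.2% and 24% unchanged genes among its calls. A simulated list of 12 genes with 2-fold changes passed camera with an estimated correlation in the 3 comparisons (adjusted p = 0.000472, 0.000149 and 0.000497, on 16400, 16411 and 16405 genes), and 0 of 25 unchanged lists did.

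Some named genes share exon bases with another gene in the annotation of this build. On the opposite strand these are Rarb (34.1% of its exon bases, with Top2b), Bmp5 (46.7%, with a gene at 0 counts), Kcnj3 (31.1%), Fgf15 (24.9%), Hoxa7 (20.4%, with Hoxaas3), Sox17 (16.8%), Nkx1-2 (16.6%), Shh (15.7%), Efna3 (14.1%), Nkx6-2 (12.9%, with Inpp5a), Ccna2 (12.5%, with Exosc9) and Junb (7.5%, with Prdx2). On the same strand Khdc3 shares 38.5% with a gene at 0 counts and Hoxc5 5.4% with Hoxc10. The strongest reason for doubt lies where the partner has many counts: Top2b had 74825 counts over the 9 libraries against 5468 for Rarb, and Prdx2 had 94623 against 2434 for Junb. If strand was ignored in the counting, reads of such partners cannot be told from those of the gene named.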

Results

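RNA was counted in 9 libraries of sorted cells from mouse neural tube organoids, which are cultures grown clonally in Matrigel from R1 embryonic stem cells, per the labels' protocols. The cells carried FoxA2-Venus, a fluorescent reporter on Foxa2, and were sorted with a GFP filter set. The libraries fall into 3 groups of 3 biological replicates each. GFP- cells and GFP+ cells came from medium with retinoic acid (RA), and a further group of GFP+ cells came from medium with SAG, an agonist of the hedgehog signal transducer Smoothened. The medium was changed at Day 2, and RNA was taken 66 h later, per the labels' protocols. Total counts ranged from 25281871 to 29763765 per library. Expression is given in CPM, which are counts scaled by the library's total times its TMM scaling factor. Values are the mean ± SD of the 3 libraries of a group (n = 3). Log2 fold changes are given with their standard error (SE).

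Foxa2, the gene behind the sort, separated the groups in the direction of the sort in every library. Foxa2 (ENSMUSG00000037025, chromosome 2, 148042877 to 148046969, minus strand, GRCm38) stood at 2.47, 1.33 and 2.51 CPM in replicates 1 to 3 of the GFP- libraries under RA. It stood at 184, 157 and 133 CPM in the GFP+ libraries under RA, and at 326, 212 and 205 CPM in the GFP+ libraries under SAG. On the first principal component of log2 CPM, which held 51.5% of the variance, the SAG libraries lay apart from both RA groups. The second component, with 24.5% of the variance, parted the GFP- from the GFP+ libraries under RA. Correlations of log2 CPM between libraries were 0.970 to 0.986 within groups and 0.887 to 0.951 between groups. These are across genes, which are not independent replicates. On the third component, with 7.9% of the variance, scores fell from replicate 1 to 3 in each group (21.6, 10.1 and -32.3 in GFP- and 7.9, 4.3 and -26 in GFP+ libraries under RA, and 55, -10 and -30.8 under SAG).

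**Figure D1:**
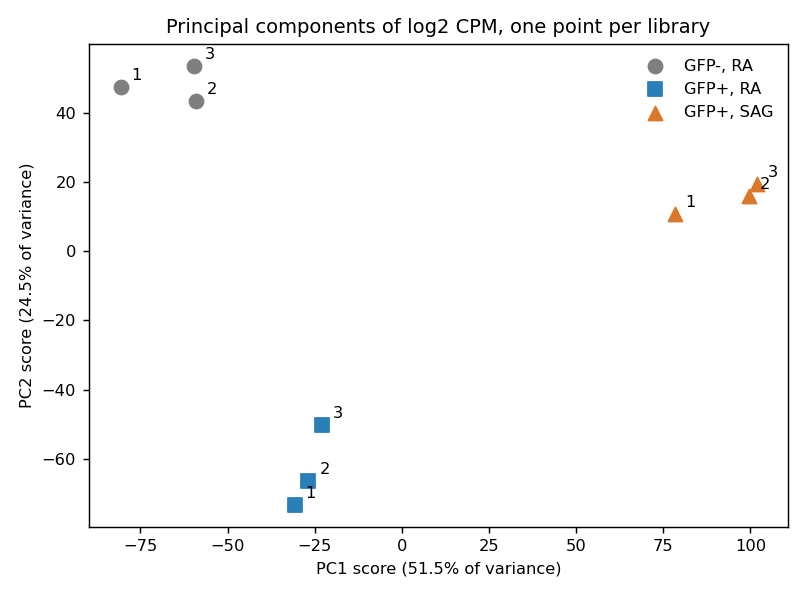
Scores of the 9 libraries on the first principal component (horizontal axis, 51.5% of the variance) and the second (vertical axis, 24.5%) of log2 CPM, 1 point per library with its replicate number, coloured by group. The 3 groups form separate clusters, with the SAG libraries at the right and the RA groups parted on the vertical axis.

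The comparison of GFP+ with GFP- cells under RA asks which genes go with FoxA2-Venus expression inside RA-treated organoids. Shh, the signal that floor plate cells secrete, stood at 0.147 ± 0.068 CPM in GFP- and 16.2 ± 4.76 CPM in GFP+ libraries (log2 fold change 6.73, SE 0.52, adjusted p = 1.44e-05). Foxa2 differed by 6.22 (SE 0.29, adjusted p = 8.39e-07), a 74.7-fold difference. Foxa1 rose from 1.94 ± 0.551 to 52.3 ± 19.3 CPM (log2 fold change 4.75, SE 0.34, adjusted p = 1.08e-05). The sulfatase gene Sulf1 rose from 59.7 ± 15.0 to 342 ± 40.4 CPM (2.52, SE 0.19, adjusted p = 1.31e-05). Of the 11 tested floor plate genes, 8 were higher and 0 lower (9 and 0 adjusted over the list alone), and the list stood above other genes (camera adjusted p = 4.35e-17, and adjusted p = 0.03 with an estimated correlation). Spon1, Ntn1, Slit1 and Slit3 were among the other called floor plate genes. Slit2, Foxj1 and Lmx1b were not called, and Ferd3l and Corin were too low to test. Shh (ENSMUSG00000002633, chromosome 5, 28456815 to 28467256, minus strand, GRCm38) shares 15.7% of its exon bases with a gene on the opposite strand that had 46 counts over the 9 libraries, against 1824 for Shh.

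Among ventral progenitor genes, Nkx6-1 rose from 4.24 ± 0.436 to 62.0 ± 3.24 CPM (log2 fold change 3.87, SE 0.16, adjusted p = 7.46e-07) and Nkx2-2 from 0.0861 ± 0.0418 to 2.44 ± 0.806 CPM (4.74, SE 0.43, adjusted p = 3.65e-05). Counting Nkx2-9 and Nkx6-2, 4 of the 6 members were higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 4.42e-13, and adjusted p = 0.00643 with an estimated correlation). Olig2, a marker of motor neuron progenitors, was not called. It stood at 1.14 ± 0.557 and 4.79 ± 4.44 CPM, with overlapping libraries (log2 fold change 2.07, SE 0.70, adjusted p = 0.0645). That call rests on single libraries, since the adjusted p was 0.017 without RA GFP+ replicate 1 (log2 fold change 2.54), 0.0468 without SAG replicate 1 and 0.307 without RA GFP+ replicate 3 (1.03). Over all alternatives the adjusted p of Olig2 ran from 1.86e-05 without the low-count filter to 0.364, and it was 0.00972 (1.77) with a replicate block in the 6 RA libraries. Of the 4 hedgehog-induced targets, the receptor gene Ptch1 rose from 310 ± 32.3 to 1290 ± 247 CPM (log2 fold change 2.06, SE 0.15, adjusted p = 1.23e-05), Gli1 rose by 1.22 (SE 0.19, adjusted p = 0.00104). Hhip was also higher. The targets gave 3 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 5.58e-06, and adjusted p = 0.0711 with an estimated correlation).

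Genes of more dorsal progenitors went the other way. Pax6 fell from 125 ± 25 to 22.3 ± 12.1 CPM (log2 fold change -2.49, SE 0.44, adjusted p = 0.00281) and Prdm12 from 5.50 ± 1.97 to 0.834 ± 0.523 CPM (-2.70, SE 0.50, adjusted p = 0.00355; -3.31 without RA GFP+ replicate 2). In all, 4 of 7 intermediate progenitor genes were lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.000198, and adjusted p = 0.211 with an estimated correlation). Pax3 fell from 54.8 ± 10.3 to 11.3 ± 3.13 CPM (-2.27, SE 0.36, adjusted p = 0.00131) and Msx3 from 17.4 ± 4.87 to 3.67 ± 1.55 CPM (-2.24, SE 0.39, adjusted p = 0.00234). Of the 13 tested dorsal and roof plate genes, 7 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 9.04e-05, and adjusted p = 0.101 with an estimated correlation). The higher one was Msx1 (14.8 ± 5.47 to 57.7 ± 19.9 CPM, log2 fold change 1.96, SE 0.51, adjusted p = 0.0198), a dorsal gene that is also a target of BMP signals. Its call was lost without RA GFP- replicate 2 (adjusted p = 0.0798), RA GFP- replicate 3 (0.0607) or RA GFP+ replicate 1 (0.0761) and in DESeq2 (0.0563), within a range of 5.31e-10 to 0.179 over the alternatives. The 8 neural crest genes split, with 2 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.937). Ets1 rose by 1.91 (SE 0.25, adjusted p = 0.000479), while Foxd3 fell by 5.11 (SE 0.99, adjusted p = 0.00446; by 6.57 without RA GFP+ replicate 2), from 2.19 ± 1.39 to 0.0564 ± 0.0698 CPM.

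General neural genes were lower in GFP+ cells. Sox1 fell from 69.7 ± 8.03 to 33.4 ± 5.74 CPM (log2 fold change -1.06, SE 0.15, adjusted p = 0.000694) and Fabp7 from 96.0 ± 32.8 to 5.34 ± 1.07 CPM (-4.16, SE 0.28, adjusted p = 6.29e-06). Of 8 pan-neural progenitor genes, 6 were lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 1.14e-07, and adjusted p = 0.0711 with an estimated correlation). Cdh2 and Prom1 were the members not called. Of 17 tested genes of neurons and neurogenesis, 13 were lower and 2 higher (13 and 3 adjusted over the list alone; camera adjusted p = 1.56e-07, and adjusted p = 0.181 with an estimated correlation). Stmn2 fell from 28.0 ± 4.67 to 7.07 ± 1.04 CPM (-1.99, SE 0.23, adjusted p = 0.000177). The higher ones were Isl1 and Mnx1, which mark motor neurons in the spinal cord. Mnx1 rose from 1.35 ± 0.238 to 9.66 ± 1.86 CPM (2.83, SE 0.28, adjusted p = 7.22e-05). In the Notch pathway, Hes1 rose by 1.48 (SE 0.17, adjusted p = 0.000177) and the ligand gene Dll3 fell by 1.68 (SE 0.15, adjusted p = 3.49e-05). The 12 Notch genes gave 3 higher and 5 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.0389, and adjusted p = 0.467 with an estimated correlation). This list's call was lost without RA GFP- replicate 3 (adjusted p = 0.0745), RA GFP+ replicate 1 (0.0545) or replicate 2 (0.0702), and SAG replicate 1 (0.114) or replicate 3 (0.0789), within a range of 0.000951 to 0.467 over the alternatives.

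**Figure D2:**
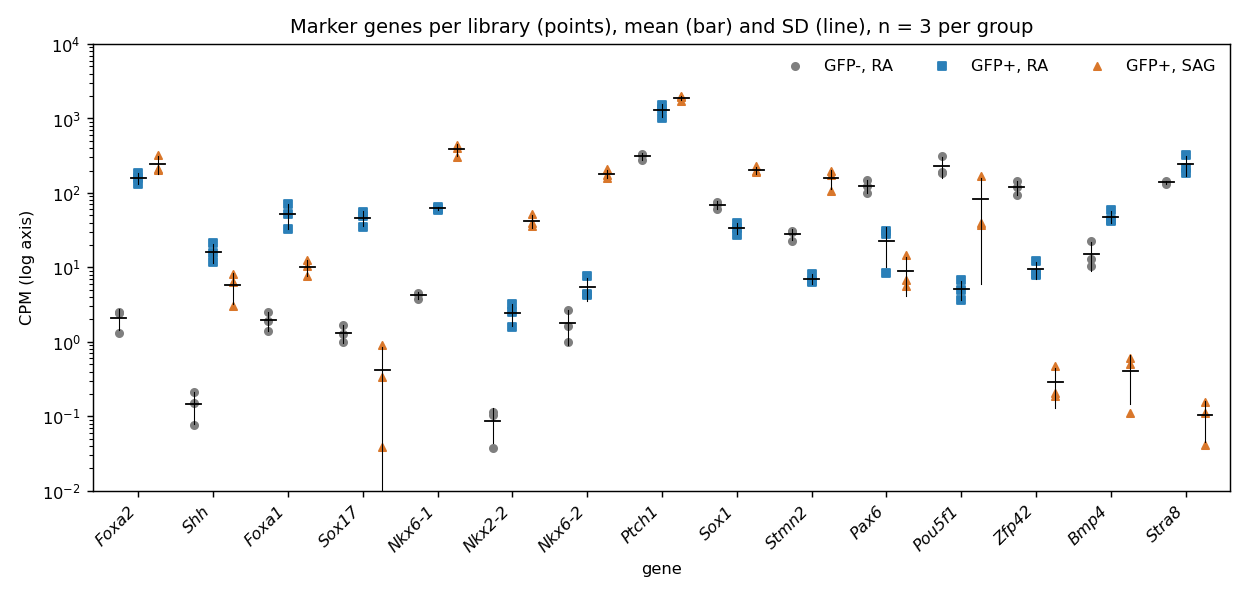
CPM (vertical log axis) of 15 genes (horizontal axis) in each of the 9 libraries, with points coloured by group, a bar at the mean and a line for the SD (n = 3 per group); the line of Sox17 under SAG, where the SD exceeds the mean, ends at the axis. Shh and Foxa1 are highest in the GFP+ libraries under RA, Nkx6-1, Nkx2-2 and Nkx6-2 in those under SAG, and Stra8 and Bmp4 fall far below both RA groups under SAG.

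Among signalling genes, Bmp7 rose from 19.5 ± 2.77 to 75.2 ± 2.20 CPM (log2 fold change 1.95, SE 0.15, adjusted p = 1.55e-05), Bmp5 from 0.175 ± 0.0828 to 3.02 ± 0.969 CPM (4.08, SE 0.54, adjusted p = 0.000467), and the BMP antagonist Nog from 0.923 ± 0.338 to 6.10 ± 2.17 CPM (2.72, SE 0.47, adjusted p = 0.00229). Among 12 BMP ligands and antagonists, 7 were higher and 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 1.16e-05, and adjusted p = 0.0522 with an estimated correlation). The 10 BMP targets did not follow as a set, with Msx1 and Bambi higher and 0 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.962). Their median log2 fold change was -0.15, their mean 0.11 and the test's direction down. Bambi rose by 0.93 (SE 0.24, adjusted p = 0.0202), but not past the threshold without RA GFP- replicate 3 (0.0671), RA GFP+ replicate 1 (0.0953) or RA GFP+ replicate 2 (0.0691), within a range of 0.00166 to 1 over the alternatives. The WNT antagonist Dkk1 rose from 0.687 ± 0.631 to 15.2 ± 10.1 CPM (4.44, SE 0.71, adjusted p = 0.00143; 5.54 without RA GFP- replicate 1 and 3.76 without RA GFP+ replicate 1). Axin2 rose by 0.81 (SE 0.19, adjusted p = 0.0143), a call lost without RA GFP- replicate 3 (0.0505) or RA GFP+ replicate 1 (0.0638), within a range of 9.09e-05 to 1. Of 10 WNT targets, 6 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.00189, and adjusted p = 0.368 with an estimated correlation).

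Among the 11 genes of the RA response, the RA transporter gene Stra6 rose from 10.8 ± 2.47 to 71.6 ± 12.4 CPM (log2 fold change 2.73, SE 0.27, adjusted p = 7.02e-05) and Nrip1 from 69.6 ± 15.8 to 142 ± 36.5 CPM (1.03, SE 0.22, adjusted p = 0.00786). With Stra8 higher and Crabp2 lower, that list gave 3 higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.321 with an estimated correlation). Its call was lost without RA GFP- replicate 2 (adjusted p = 0.0501) or RA GFP+ replicate 3 (0.0841), within a range of 0.000675 to 0.321. FGF genes split, with Il17rd higher by 1.01 (SE 0.18, adjusted p = 0.00294) and Spry4 lower at -1.72 (SE 0.27, adjusted p = 0.00121). The 10 FGF ligands and targets gave 2 higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.937), with a median of 0.18, a mean of -0.03 and the test's direction down. Of 8 hedgehog pathway components and repressed genes, Boc fell from 128 ± 28.9 to 46.4 ± 7.40 CPM (-1.46, SE 0.18, adjusted p = 0.000322) and Scube2 fell by 3.00 (SE 0.51, adjusted p = 0.002). That list gave 2 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.361). It passed without RA GFP- replicate 1 (0.0362), within a range of 0.0362 to 0.856.

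Genes of position along the head-to-tail axis did not pass the test as sets. Of 12 tested forebrain and midbrain genes, 3 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.962; median -0.06, mean 0.06, test direction down). En2 fell from 20.7 ± 5.86 to 3.26 ± 1.71 CPM (log2 fold change -2.66, SE 0.40, adjusted p = 0.00104) and Lhx5 fell by 3.53 (SE 0.45, adjusted p = 0.000353), while Six3, Lhx2 and Nkx2-1 were higher. The 13 tested genes in the list of the hindbrain and Hox groups 1 to 4 gave 2 higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.958). Of 12 tested genes in Hox groups 5 to 9, Hoxc8 (2.67, SE 0.52, adjusted p = 0.00455; 2.02 without RA GFP+ replicate 1) and Hoxc9 (3.15, SE 0.49, adjusted p = 0.00123) were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.962). Members that were not called varied with the replicate number. Hoxb8 stood at 37.3, 37.8 and 99.3 CPM in GFP- and 7.17, 16.9 and 49.3 CPM in GFP+ replicates 1 to 3. Hoxb5, Hoxb6, Hoxb7, Hoxb9, Hoxc5 and Hoxc6 also stood below GFP- in each same-numbered pair, while Hoxa5, Hoxa7 and Hoxa9 were mixed.

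Pluripotency genes were far higher in GFP- cells. Zfp42 stood at 120 ± 24.9 CPM in GFP- and 9.46 ± 2.37 CPM in GFP+ libraries (log2 fold change -3.67, SE 0.24, adjusted p = 5.98e-06), and Esrrb at 135 ± 22.1 and 11.7 ± 2.87 CPM (-3.52, SE 0.21, adjusted p = 3.47e-06). Of 11 genes, 8 were lower and 1, Lin28a, higher, the same adjusted over the list alone (camera adjusted p = 2.44e-21, and adjusted p = 0.03 with an estimated correlation). Among the 5 lowest genes, Tcl1 fell by 6.24 (SE 0.74, adjusted p = 0.000229; by 7.13 without RA GFP+ replicate 2), Tdgf1 fell by 6.01 (SE 0.86, adjusted p = 0.000726; by 7.1 without RA GFP+ replicate 3), and Tdh fell from 172 ± 55.0 to 2.57 CPM (-6.06, SE 0.44, adjusted p = 1.11e-05). Platr10 (-5.77, SE 0.60, adjusted p = 9.23e-05) and Calcoco2 (-5.60, SE 0.35, adjusted p = 3.47e-06) completed them. At the other extreme, beside Shh and Foxa2, stood Dcn (6.89, SE 0.93, adjusted p = 0.000503; 8.43 without RA GFP- replicate 2), Osr1 (6.25, SE 0.62, adjusted p = 0.000177; 6.89 without RA GFP- replicate 1) and Foxf2 (6.07, SE 0.62, adjusted p = 8.01e-05; 7.22 without RA GFP- replicate 3), which are known from mesenchyme and reached 7.94 ± 3.61, 5.04 and 6.14 CPM.

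Several endoderm genes were higher in GFP+ cells. Sox17 rose from 1.33 ± 0.353 to 46.3 ± 10.6 CPM (log2 fold change 5.12, SE 0.48, adjusted p = 4.73e-05). Afp had 0 counts in the GFP- libraries and was at least 29.5-fold higher in GFP+ libraries. Of 11 tested genes of endoderm, node and notochord, 6 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.000178, and adjusted p = 0.181 with an estimated correlation). T, a notochord gene of the list, was not called (1.24, 1.03 and 0.228 CPM in GFP- and 7.68, 2.69 and 1.57 CPM in GFP+ replicates 1 to 3). Chrd of the same list stood at 4.7, 4.31 and 6.51 CPM in GFP- and 21.6, 17.3 and 13.6 CPM in GFP+ replicates 1 to 3. In the mesoderm list, Foxc2 rose by 3.96 (SE 0.44, adjusted p = 0.000152) and Tcf15 fell by 2.42 (SE 0.34, adjusted p = 0.000602). The 9 tested mesoderm genes gave 4 higher and 1 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.201), and the list passed without RA GFP+ replicate 1 (0.0103), within a range of 0.0103 to 0.446. Of 6 tested surface ectoderm genes, Trp63 rose by 4.22 (SE 0.68, adjusted p = 0.00143; 4.95 without RA GFP- replicate 2) and Grhl3 fell by 2.07 (SE 0.33, adjusted p = 0.00142). That list gave 2 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.962; median 0.18, mean 0.57, test direction down).

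No cell state list passed the test under the sort. Of 12 cell cycle genes, Pcna alone was called, falling from 261 ± 37.2 to 185 ± 10.7 CPM (0 higher and 1 lower; 0 and 3 adjusted over the list alone; camera adjusted p = 0.299). The adjusted p of Pcna (log2 fold change -0.50, SE 0.13, adjusted p = 0.0199) rose to 0.0626 without RA GFP- replicate 1, 0.067 without RA GFP- replicate 2, 0.0796 without RA GFP+ replicate 2 and 0.0737 without RA GFP+ replicate 3, within a range of 0.00239 to 1. Of 10 tested genes of dissociation and immediate early stress, 3 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.141). With the replicate number as a block this list passed (adjusted p = 0.0437), within a range of 0.00444 to 0.268. Jun rose by 1.52 (SE 0.23, adjusted p = 0.000942) and Dusp1 fell by 1.10 (SE 0.17, adjusted p = 0.0013). Of 11 genes of hypoxia and glycolysis 0 were called, also over the list alone (camera adjusted p = 0.937). The nearest, Slc2a1, differed by 0.55 (SE 0.25, adjusted p = 0.164), and by 0.59 with the block (adjusted p = 0.0467), within a range of 0.00275 to 1. Ldha of that list followed the replicate number, with 1090, 137 and 1410 CPM in GFP- and 930, 116 and 1370 CPM in GFP+ replicates 1 to 3. Among 21 cadherins, Eph receptors and ephrins, 6 were higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.339; median 0.18, mean -0.01, test direction up). Ephb3 rose by 1.62 (SE 0.18, adjusted p = 0.000163) and Pcdh8 fell by 2.3 (SE 0.35, adjusted p = 0.00108).

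Across 16772 tested genes, 1424 were higher and 1414 lower in GFP+ than in GFP- cells under RA, 16.9% of those tested, of which 777 and 1026 differed by more than 2-fold. The counts fell to 893 and 890 without RA GFP+ replicate 2, and the lower count to 915 without RA GFP+ replicate 1. With a replicate block in the 6 RA libraries, a fit chosen after seeing the data, they rose to 2615 and 2625. In simulated data for this comparison (16408 genes), 92% of 4-fold changes and 56% of 2-fold changes were found, so a gene that was not called may still differ by 2-fold.

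**Figure D3:**
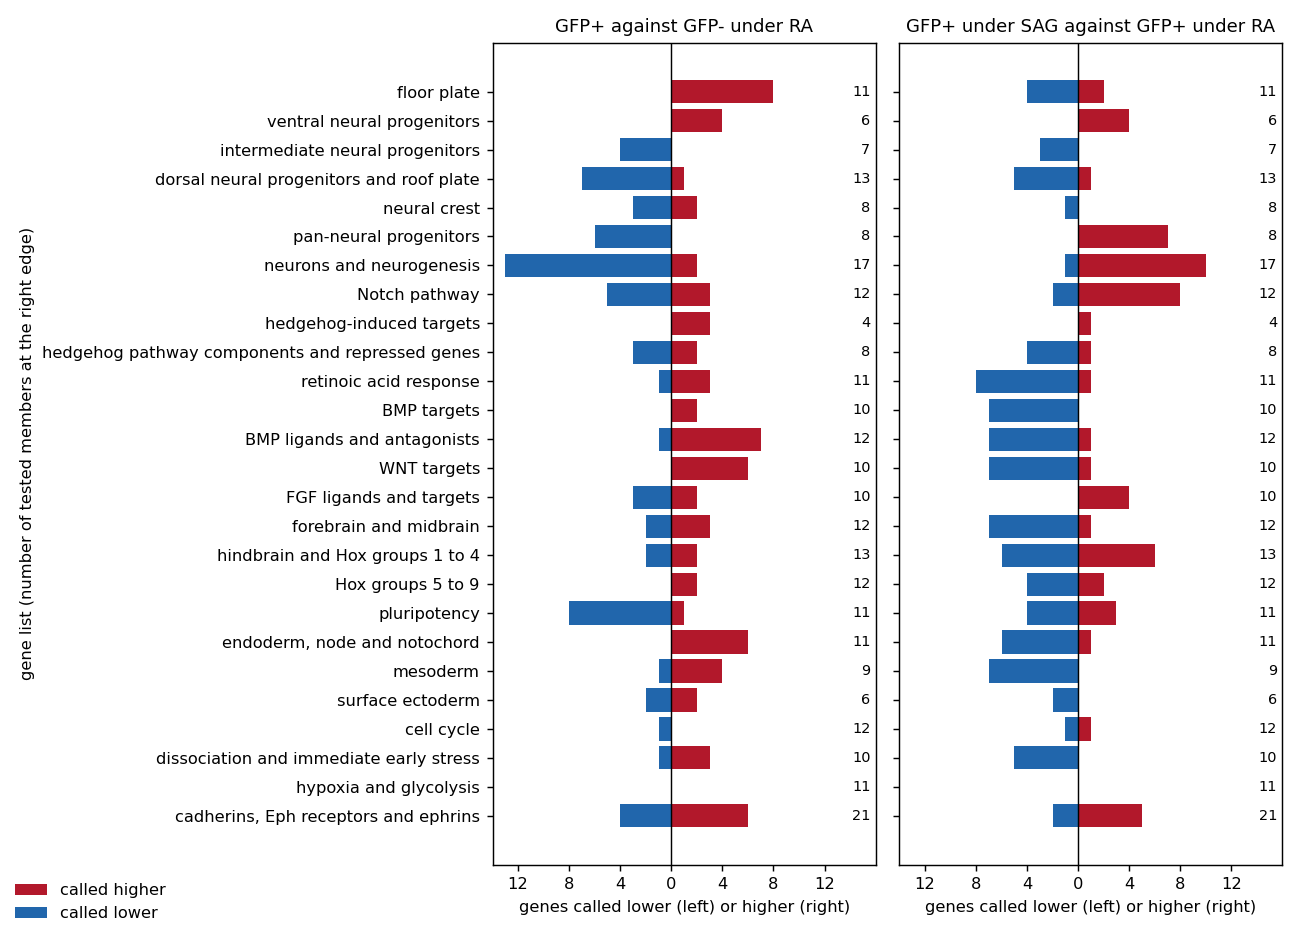
Number of genes called higher (right, red) or lower (left, blue) in each of the 26 gene lists (vertical axis), for GFP+ against GFP- cells under RA and for GFP+ cells under SAG against GFP+ cells under RA, with the number of tested members at the right edge. Floor plate genes are higher in 8 of 11 members under the sort. Pan-neural genes have 6 lower in the left panel and 7 higher in the right. GFP+ under RA is the first group on the left and the reference on the right, so lists unusual in it turn sign between the panels.

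The comparison of GFP+ cells under SAG with GFP+ cells under RA asks how cells with the same reporter differ between these media. SAG medium is taken to lack RA. With no group that had both or neither, added SAG and missing RA cannot be told apart. Nkx6-1 stood at 62.0 ± 3.24 CPM under RA and 386 ± 70.5 CPM under SAG (log2 fold change 2.64, SE 0.15, adjusted p = 1.04e-06), and Nkx6-2 at 5.41 ± 1.90 and 181 ± 24.7 CPM (5.06, SE 0.32, adjusted p = 2.55e-06). Nkx2-2 (ENSMUSG00000027434, chromosome 2, 147177546 to 147194243, minus strand, GRCm38) and Olig1 were also higher. In all, 4 of 6 ventral progenitor genes were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 2.12e-11, and adjusted p = 0.0085 with an estimated correlation). Nkx6-2 shares 12.9% of its exon bases with Inpp5a on the opposite strand. Floor plate genes divided. Shh fell from 16.2 ± 4.76 to 5.88 ± 2.66 CPM (-1.46, SE 0.36, adjusted p = 0.0128), Foxa1 from 52.3 ± 19.3 to 10.2 ± 2.53 CPM (-2.35, SE 0.30, adjusted p = 0.000215) and Lmx1b from 46.2 ± 9.23 to 14.2 ± 4.65 CPM (-1.70, SE 0.23, adjusted p = 0.000344). With Slit3 and Sulf1 higher, the 11 tested genes gave 2 higher and 4 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.515).

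Foxa2 itself was slightly higher under SAG (158 ± 25.8 to 248 ± 68.2 CPM, log2 fold change 0.65, SE 0.22, adjusted p = 0.0497). That call is at the threshold, and it was lost without RA GFP- replicate 3 (adjusted p = 0.0519), RA GFP+ replicate 1 (0.0574), replicate 2 (0.135) or replicate 3 (0.147), SAG replicate 1 (0.132, log2 fold change 0.42) or SAG replicate 2 (0.0549), within a range of 0.00085 to 1. Ptch1 rose from 1290 ± 247 to 1890 ± 136 CPM (0.55, SE 0.15, adjusted p = 0.0187), a call lost without RA GFP+ replicate 2 (0.052), RA GFP+ replicate 3 (0.0642) or SAG replicate 3 (0.054), within a range of 0.00107 to 1. Gli1 and Hhip were not called, and the list of hedgehog-induced targets gave 1 higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.187). Olig2 was not called either (4.79 ± 4.44 to 13.2 ± 7.52 CPM, 1.46, SE 0.64, adjusted p = 0.123). Without RA GFP+ replicate 3 it passed (2.5, adjusted p = 0.0148), and without SAG replicate 1 it stood at 0.93 (adjusted p = 0.313), within a range of 0.00144 to 0.685. Genes for hedgehog co-receptors fell, with Cdon going from 136 ± 39.7 to 33.3 ± 1.69 CPM (-2.03, SE 0.23, adjusted p = 0.000104) and Boc from 46.4 ± 7.40 to 17.8 ± 1.47 CPM (-1.39, SE 0.18, adjusted p = 0.000284). The 8 hedgehog pathway components and repressed genes gave 1 higher and 4 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.0103, and adjusted p = 0.357 with an estimated correlation).

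Some dorsal and intermediate genes were lower under SAG than in GFP+ cells under RA. Pax3 fell from 11.3 ± 3.13 to 0.0950 ± 0.165 CPM (log2 fold change -6.89, SE 0.58, adjusted p = 1.52e-05). It stood at -6.28 without SAG replicate 2, and at -11.26 without SAG replicate 1, where the count under SAG is 0. Msx2 fell from 6.01 ± 1.07 to 0.459 ± 0.171 CPM (-3.70, SE 0.34, adjusted p = 2.47e-05). Of 13 tested dorsal and roof plate genes, 5 were lower and 1, Olig3, higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.000209, and adjusted p = 0.0897 with an estimated correlation). Dbx1 fell from 3.35 ± 3.21 to 0.0634 ± 0.0576 CPM (-5.60, SE 1.14, adjusted p = 0.00406; -4.53 without RA GFP+ replicate 3 and -6.23 without SAG replicate 2). Prdm12 had 1 count over the SAG libraries, in replicate 1, a ratio of 66.0 (95% counting interval 11.5 to 2640). Its log2 fold change was -5.58, and -4.96 without RA GFP+ replicate 2 and -7.51 without SAG replicate 1, where the count is 0. The 7 intermediate progenitor genes gave 3 lower and 0 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.425). Of 8 neural crest genes, Sox10 alone was called, falling by 3.82 (SE 0.54, adjusted p = 0.000391; 0 higher and 1 lower, the same adjusted over the list alone; camera adjusted p = 0.733; median 0.09, mean -0.36, test direction down).

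General neural and neuronal genes were higher under SAG than in GFP+ cells under RA. Sox1 rose from 33.4 ± 5.74 to 203 ± 20.8 CPM (log2 fold change 2.60, SE 0.16, adjusted p = 1.97e-06) and Fabp7 from 5.34 ± 1.07 to 55.4 ± 8.45 CPM (3.37, SE 0.27, adjusted p = 1.1e-05). Of 8 pan-neural genes, 7 were higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 3.23e-09, and adjusted p = 0.0537 with an estimated correlation), and Vim was the member not called. Stmn2 rose from 7.07 ± 1.04 to 159 ± 46.2 CPM (4.49, SE 0.25, adjusted p = 9.07e-07). Of 17 tested genes of neurons and neurogenesis, 10 were higher and 1, Mnx1, lower, the same adjusted over the list alone (camera adjusted p = 1.72e-08, and adjusted p = 0.157 with an estimated correlation). In the Notch pathway, Lfng rose by 2.49 (SE 0.20, adjusted p = 1e-05) and Dll3 by 1.39 (SE 0.15, adjusted p = 6.45e-05). The 12 Notch genes gave 8 higher and 2 lower, Heyl and Jag2, the same adjusted over the list alone (camera adjusted p = 0.000209, and adjusted p = 0.202 with an estimated correlation).

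Targets of RA were lower in the medium that was labelled SAG. Stra8 (ENSMUSG00000029848, chromosome 6, 34920163 to 34939344, plus strand, GRCm38) fell from 242 ± 72.0 to 0.103 ± 0.0581 CPM (log2 fold change -11.12, SE 0.34, adjusted p = 1.78e-08), and the receptor gene Rarb from 35.6 ± 15.2 to 0.308 ± 0.214 CPM (-6.82, SE 0.53, adjusted p = 8.8e-06). Rarb shares 34.1% of its exon bases with Top2b on the opposite strand, so part of its counts could belong to Top2b. Of 11 RA response genes, 8 were lower and 1, the RA-degrading enzyme gene Cyp26b1, higher (9 and 1 adjusted over the list alone; camera adjusted p = 2.32e-08, and adjusted p = 0.0537 with an estimated correlation). Several BMP genes fell as well. Bmp4 went from 47.9 ± 8.87 to 0.410 ± 0.263 CPM (-6.87, SE 0.46, adjusted p = 3.47e-06), Twsg1 from 240 ± 20.9 to 144 ± 5.82 CPM (-0.74, SE 0.12, adjusted p = 0.000876) and Nog from 6.10 ± 2.17 to 1.49 ± 0.691 CPM (-2.03, SE 0.45, adjusted p = 0.00714). Among 12 BMP ligands and antagonists, 7 were lower and 1, Fst, higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000245, and adjusted p = 0.0537 with an estimated correlation). Of 10 BMP targets, 7 were lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 5.74e-05, and adjusted p = 0.112 with an estimated correlation), with Msx1 at -5.43 (SE 0.62, adjusted p = 9.5e-05; -6.78 without SAG replicate 1) beside Msx2.

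Most genes of the WNT target list were lower under SAG than in GFP+ cells under RA. Against GFP- cells under RA, 1 of the 10 was higher and 1 lower. Dkk1 fell from 15.2 ± 10.1 to 0.451 ± 0.387 CPM (log2 fold change -5.07, SE 0.75, adjusted p = 0.000534; -4.38 without RA GFP+ replicate 1 and -6.00 without SAG replicate 1) and Sp5 from 116 ± 45.7 to 4.27 ± 6.53 CPM (-4.78, SE 0.95, adjusted p = 0.00358; -7.84 without SAG replicate 1). Of 10 WNT targets, 7 were lower and 1, Lef1, higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.38 with an estimated correlation). Fgf15 rose from 11.7 ± 4.78 to 209 ± 1.76 CPM (4.15, SE 0.33, adjusted p = 8.9e-06) and the feedback inhibitor gene Spry2 by 0.76 (SE 0.16, adjusted p = 0.00552). The 10 FGF ligands and targets gave 4 higher and 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.357 with an estimated correlation), a call lost without SAG replicate 1 (0.0849), within a range of 0.00174 to 0.357.

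Position genes changed in part. Egr2, which marks hindbrain segments, rose from 1.24 ± 0.325 to 43.6 ± 34.6 CPM (log2 fold change 5.12, SE 0.64, adjusted p = 0.000187), with 83.5, 21.8 and 25.5 CPM in SAG replicates 1 to 3 (4.27 without SAG replicate 1). The 13 tested genes of the hindbrain and Hox groups 1 to 4 gave 6 higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.635; median 0.27, mean -0.01, test direction up). Higher were Egr2, Gbx2, Hoxb1, Hoxa2, Hoxb2 and Hoxa3, while Hoxd3, Hoxa4, Hoxb4 and Hoxc4 were among the lower ones. Forebrain and midbrain genes gave 1 higher, En1, and 7 lower of 12 tested (1 and 9 adjusted over the list alone; camera adjusted p = 0.00461, and adjusted p = 0.0744 with an estimated correlation). Dmbx1 fell by 3.15 (SE 0.41, adjusted p = 0.000239), and Hesx1 had 1 count over the SAG libraries, in replicate 2, a ratio of 218 (95% counting interval 38.8 to 8650; log2 fold change -7.34, and -9.26 without that library, where the count is 0). In Hox groups 5 to 9, Hoxc5 fell from 21.5 ± 22.8 to 0.588 ± 0.294 CPM (-5.18, SE 0.91, adjusted p = 0.0017; -3.84 without RA GFP+ replicate 3) and Hoxa7 fell by 1.23 (SE 0.30, adjusted p = 0.0106). The 12 tested members gave 2 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.635).

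Many markers of other tissues were lower under SAG than in GFP+ cells under RA. Sox17 fell from 46.3 ± 10.6 to 0.424 ± 0.435 CPM (log2 fold change -6.77, SE 0.55, adjusted p = 1.1e-05; -7.87 without SAG replicate 1). Afp had 0 counts in the SAG libraries and was at least 28.1-fold lower. The 11 tested genes of endoderm, node and notochord gave 6 lower and 1, T, higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.00409, and adjusted p = 0.212 with an estimated correlation). In the mesoderm list Foxc2 fell by 1.93 (SE 0.39, adjusted p = 0.00408), Hand1 had 1 count over the SAG libraries, in replicate 1, a ratio of 271 (95% counting interval 48.3 to 10800; log2 fold change -7.65, and -9.59 without that library, where the count is 0). In all, 7 of 9 tested genes were lower and 0 higher, the same adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.202 with an estimated correlation). The mesoderm call was lost without SAG replicate 1 (0.0581), within a range of 0.000759 to 0.202. Of 6 surface ectoderm genes, Trp63 fell by 2.5 (SE 0.59, adjusted p = 0.00956) and Grhl3 by 1.28 on the log2 scale, and 0 were higher (2 lower; 4 adjusted over the list alone; camera adjusted p = 0.0671). This list passed without RA GFP+ replicate 2 (0.0252) or SAG replicate 1 (0.0045), within a range of 0.0045 to 0.278. The call of Grhl3 (log2 fold change -1.28, SE 0.34, adjusted p = 0.0175) was lost without RA GFP+ replicate 2 (0.0768), SAG replicate 2 (0.0709) or SAG replicate 3 (0.0569), within a range of 0.000415 to 0.521.

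Pluripotency genes split between the media. Zfp42 fell from 9.46 ± 2.37 to 0.286 ± 0.157 CPM (log2 fold change -5.02, SE 0.34, adjusted p = 3.47e-06) and Dppa5a from 13.1 ± 2.16 to 0.793 ± 0.488 CPM (-4.05, SE 0.34, adjusted p = 1.52e-05). Pou5f1, Nanog and Tdgf1 were higher, and Pou5f1 stood at 171, 37.4 and 39.3 CPM in SAG replicates 1 to 3, against 5.14 ± 1.5 CPM under RA. The 11 genes gave 3 higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.0585; median 0.03, mean -0.22, test direction down). The list passed without RA GFP- replicate 2 (0.0428), RA GFP+ replicate 1 (0.0197) or RA GFP+ replicate 2 (0.0181), within a range of 0.0181 to 0.422. Some immediate early genes fell, with Junb going from 20.4 ± 4.84 to 1.97 ± 0.682 CPM (-3.37, SE 0.34, adjusted p = 4.1e-05) and Egr1 from 22.1 ± 0.398 to 2.5 ± 1.12 CPM (-3.14, SE 0.31, adjusted p = 3.94e-05). The 10 tested genes of dissociation and immediate early stress gave 5 lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.00116, and adjusted p = 0.0537 with an estimated correlation).

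Of 12 cell cycle genes under SAG, 1 was higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.21). Ccna2 rose by 0.36 (SE 0.12, adjusted p = 0.0474), a call lost in DESeq2 (0.0598), without the low-count filter (0.0662) and without RA GFP- replicate 2 (0.066), RA GFP+ replicate 1 (0.196) or 2 (0.17), or SAG replicate 1 (0.0603), 2 (0.0953) or 3 (0.104), within a range of 0.0224 to 1. Ccne1 fell by 0.77 (SE 0.21, adjusted p = 0.0223), a call lost without RA GFP+ replicate 1 (0.0733) or 2 (0.0759) and SAG replicate 2 (0.0933) or 3 (0.0901), within a range of 7.12e-05 to 1. Of 11 genes of hypoxia and glycolysis 0 were called, also over the list alone (camera adjusted p = 0.733). Slc2a1 lay at the threshold (-0.73, SE 0.25, adjusted p = 0.0516). It passed in DESeq2 (0.0232), without the low-count filter (8.19e-05), with only the 6 libraries compared (0.0265) and without RA GFP- replicate 2 (0.0185), RA GFP- replicate 3 (0.037) or RA GFP+ replicate 2 (0.0407), within a range of 8.19e-05 to 1. Among 21 cadherins, Eph receptors and ephrins, 5 were higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.192). The lower ones were Efna1, from 10 ± 2.9 to 3.24 ± 1.28 CPM (log2 fold change -1.63, SE 0.34, adjusted p = 0.00472), and Efna3, from 20.8 ± 4.22 to 9.38 ± 1.86 CPM (-1.15, SE 0.22, adjusted p = 0.00259).

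Across the same 16772 genes, 1641 were higher and 2476 lower in GFP+ cells under SAG than in GFP+ cells under RA, 24.5% of those tested, of which 903 and 1696 differed by more than 2-fold. The higher count fell to 954 without RA GFP+ replicate 1 and to 957 without RA GFP+ replicate 2. Timp4 (0.195 to 47.1 ± 5.12 CPM, log2 fold change 7.91, SE 0.65, adjusted p = 1.18e-05), Kcnj3 (0.261 to 31.2 CPM, 6.87, SE 0.41, adjusted p = 1.96e-06), Neurod4 (6.30, SE 0.58, adjusted p = 2.46e-05) and Ppp1r17 (5.85, SE 0.72, adjusted p = 0.000172) were among the 5 highest. The fifth, Nkx1-2, a gene of the caudal epiblast, stood at 139, 9.93 and 3.78 CPM in SAG replicates 1 to 3 (7.04, SE 1.36, adjusted p = 0.00313; 4.16 without SAG replicate 1). At the other end, beside Stra8, Fbxo40 (at least 156-fold lower), Rhox6 (at least 151-fold) and Osr1 (at least 129-fold) had 0 counts in the SAG libraries. Khdc3 had 1 count there, in replicate 2, a ratio of 1180 (95% counting interval 212 to 46800; log2 fold change -9.79, and -11.71 without that library, where the count is 0). In simulated data for this comparison (16400 genes), 94% of 4-fold changes and 52% of 2-fold changes were found.

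GFP+ cells under SAG were also set against GFP- cells under RA, where sort and medium differ together and cannot be told apart. Foxa2 differed by 6.87 (SE 0.29, adjusted p = 9.76e-08) and Nkx2-2 by 8.85 (SE 0.41, adjusted p = 1.39e-07), from 0.0861 ± 0.0418 to 42.2 ± 8.34 CPM. Timp4 (6.94, SE 0.60, adjusted p = 1.23e-05; 8.9 without RA GFP- replicate 1) and Nkx6-2 (6.68, SE 0.35, adjusted p = 3.96e-07) were also among the highest genes. Lowest were Rhox6 (at least 650-fold lower), Dazl (at least 377-fold), Prdm14 (at least 350-fold) and Ooep (at least 307-fold), with 0 counts under SAG, and Calcoco2 with 1 count, in SAG replicate 3, a ratio of 4010 (95% counting interval 719 to 158000; log2 fold change -11.52, and -13.45 without that library, where the count is 0). In all 2014 genes were higher and 2773 lower, 28.5% of those tested. Of the lists, ventral progenitors (6 of 6 higher, camera adjusted p = 2.33e-25), dorsal and roof plate genes (10 of 13 lower, 1.46e-09) and pluripotency genes (9 of 11 lower and 2 higher, 3.78e-17) kept their call with an estimated correlation (adjusted p = 0.000875, 0.0377 and 0.0406). Floor plate genes (7 higher and 1 lower of 11, camera adjusted p = 2.54e-09, and adjusted p = 0.106 with an estimated correlation) and hedgehog-induced targets (4 of 4 higher, 1.72e-06, and adjusted p = 0.062 with an estimated correlation) did not. BMP targets (0 higher and 6 lower of 10, 0.000102) and the RA response (2 and 5 of 11, 0.000779) also lost their call (0.128 and 0.159). Pan-neural progenitors (2 and 1 of 8) and neurons (6 and 5 of 17) were not called (camera adjusted p = 0.296 each). Nor were WNT targets (1 and 1 of 10, 0.998), BMP ligands and antagonists (3 and 5 of 12, 0.971), endoderm (2 and 2 of 11, 0.971) or mesoderm (2 and 3 of 9, 0.583).

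Both GFP+ populations were compared with the same GFP- libraries, to ask which differences from GFP- cells under RA are found in both. For the SAG population sort and medium differ together. The overlap therefore does not show which genes go with the reporter under SAG. In the same direction in both comparisons, 558 genes were higher and 870 lower, and 207 were called in opposite directions. The higher genes included Foxa2, 7 floor plate genes (Shh, Ntn1, Foxa1, Spon1, Slit1, Slit3 and Sulf1), 4 ventral progenitor genes (Nkx2-2, Nkx2-9, Nkx6-1 and Nkx6-2) and 3 hedgehog-induced targets (Gli1, Ptch1 and Hhip). The lower genes included 8 pluripotency genes and 6 dorsal genes (Pax3, Pax7, Msx3, Zic1, Gsx1 and Gsx2). Of the endoderm, node and notochord list 0 genes were shared. Independent lists of these sizes would share 171 and 234 genes, a value that leaves out the shared controls. The log2 fold changes of both comparisons correlated across genes with r = 0.512 (0.496 in 20 simulated sets of unchanged groups against the same controls), and their covariance was 0.796 (0.066 simulated, a difference of 0.73). With 3 control libraries these could not be split into parts of at least 2 each, so part of the excess over independent lists may come from the shared controls. The higher count fell to 357 without RA GFP+ replicate 2.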

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

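All alternatives were planned except the replicate block in the 6 RA libraries, which was chosen after seeing the data. No list or named gene was called in opposite directions by the planned test and an alternative.

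DESeq2-style size factors (RLE) kept every call of the 133 named gene results and 78 list results, where a gene or list counts in each comparison that tests it. They kept 2820 of 2838, 4101 of 4117 and 4768 of 4787 called genes in the 3 comparisons. The share of higher among called genes moved from 50.2% to 49.6%, from 39.9% to 40.3% and from 42.1% to 41.8%. The DESeq2 Wald test gave 1661 higher and 1747 lower genes for the sort under RA, 1938 and 2866 for SAG against RA in GFP+ cells, and 2257 and 3272 for SAG GFP+ against RA GFP-. It kept 2804, 4079 and 4720 of the called genes, and among named gene results lost 2 and gained 1. In simulated data with 200 changed genes, 24%, 22.2% and 24% of its calls were unchanged genes (46, 42 and 47 genes). A larger number of changed genes was not simulated, so how many of the added calls are changed genes is not known. Without the low-count filter 2674, 3813 and 4425 called genes kept their call, 4 named gene results and 7 list results gained a call, and 1 named gene result lost it. With only the 6 libraries compared, 2693, 3693 and 3754 called genes kept their call. The test against a fold change of 2 asks for more than a difference, and it left 292 higher and 444 lower genes for the sort under RA, 343 and 938 for SAG against RA in GFP+ cells, 323 and 1179 for SAG GFP+ against RA GFP-, and 85 and 308 shared. It kept 107 of 133 named gene results on the same side of the threshold.

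With the replicate number as a block, the sort under RA gave 1947 higher and 1864 lower genes, with 2821 of 2838 called genes kept. Where pairing by number was not shown, the block gave 2271 and 3097 (SAG against RA in GFP+ cells) and 2737 and 3441 (SAG GFP+ against RA GFP-). Shared genes rose from 558 to 881 higher and from 870 to 1131 lower. A replicate block in the 6 RA libraries gave 2615 higher and 2625 lower genes and kept 2816 of 2838. Under the sort the block in all 9 libraries changed the call of Slc2a1 and of the dissociation list, and no other call of a named gene or list. In the 6 RA libraries, where lists were not run, the block changed the calls of Slc2a1 and Olig2 and of no other named gene. In the other comparisons it brought Slc2a1 under SAG past the threshold (adjusted p = 0.0157, within a range of 8.19e-05 to 1), and the FGF and cadherin lists in SAG GFP+ against RA GFP- (0.0321 each, within ranges of 0.0081 to 0.49 and 0.00235 to 0.159 over the alternatives). The cause was not tested.

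Leaving out 1 library at a time, the sort under RA gave 893 to 1684 higher and 890 to 1684 lower genes. SAG against RA in GFP+ cells gave 954 to 2092 higher and 1712 to 2880 lower genes, SAG GFP+ against RA GFP- gave 1351 to 2581 and 2014 to 3295, and the shared genes ran from 357 to 681 and from 602 to 1035. All 8 highest counts came without SAG replicate 1. The lowest counts came without RA GFP+ replicate 1 or 2 or SAG replicate 2. Of the leave-one-out results of named genes, 1157 kept their side of the threshold, 34 lost a call and 6 gained one. Of those of the lists, 671 kept their side, 9 lost a call and 22 gained one. The genes and lists of the first 2 comparisons concerned are named in the report. For SAG GFP+ against RA GFP- the lists of neurons (adjusted p = 0.0103), Notch (0.0172) and surface ectoderm (0.00809) passed without SAG replicate 1. The FGF and cadherin lists, at 0.0584 there, passed without several single libraries. The cause was not tested.

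Among the 78 list results, 31 calls were lost when the correlation between genes was estimated from the data, and 47 results stayed on their side. In each of those 31 the estimated correlation gave the highest adjusted p of all alternatives. Self-contained tests with fry, which ask whether a list's genes move on balance one way, kept 68 results, lost 1 (Notch under the sort, 0.0565, within a range of 0.000951 to 0.467) and gained 9. In simulated data 56%, 52% and 52% of 2-fold changes were found, so a gene that was not called is not shown to be unchanged.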

Other observations

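The test of library size for the pluripotency genes was chosen only after its result was seen, as were conditions on camera, on members that go both ways and on the genes of a pattern itself, which can only move an explanation to open. The other tests were chosen before their results were seen, but the patterns were noticed in the data first. Random lists below are 10000 draws of the same size, matched on mean expression in 20 classes, given as the range of the middle 95% of their medians. Each list leaves out the genes that drew attention to it.

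Other splits of the libraries into 3 and 3 were fitted for each comparison. The real split gave 2838 called genes for the sort under RA, 4117 for SAG against RA in GFP+ cells and 4787 for SAG GFP+ against RA GFP-, and the highest of the other splits gave 0 in each. There are 10 splits, and the 1 with as many called genes is the real one itself, so they are too few for a share under 0.05.

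Pluripotency genes were far higher in GFP- than in GFP+ cells under RA. Fold changes are already scaled for library size, so setting the totals beside them is no independent test of it. The largest GFP- total exceeds the smallest GFP+ total under RA by 9.02%. The smallest change among the 8 members called lower was -3.52 on the log2 scale. Undifferentiated cells among the sorted GFP- cells are a candidate explanation. In 14 naive pluripotency genes not used to find the pattern, 12 were lower in GFP+ cells and the median was -2.25 (random lists -0.35 to 0.29; camera adjusted p = 5.26e-20, and adjusted p = 0.00772 with an estimated correlation), with Tfcp2l1 falling from 100 to 11.7 CPM and Fbxo15 from 84 to 3.88 CPM. Whether such cells are a separate population or the same genes are lower in each differentiating cell was not tested, as the libraries are bulk.

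T, Nkx1-2 and Cdx2 were highest in replicate 1 of the SAG libraries (T at 110, 7.94 and 9.81 CPM, Cdx2 at 47.5, 5.06 and 3.97 CPM in replicates 1 to 3). The total of that library lies 1.12% below the smallest other total and its scaling factor is 0.972 beside 0.976, so both are the lowest. The prediction written before counted values outside the range of the other libraries for library size, and values close to that range against it. Both conditions were met, so the prediction cannot decide. CPM are already scaled for library size, and these differences are far smaller than those of the 3 genes. More caudal epiblast-like cells in that library may be the source, but this stays open: in 7 further caudal epiblast genes the median log2 ratio to the other SAG libraries was 0.87, above random lists (-0.58 to 0.44) and below the bound of 1 set before, and that library differs more broadly, with gut endoderm genes (median 1.22) and naive pluripotency genes (0.40, random lists -0.37 to 0.29) higher there and visceral motor neuron genes lower (-1.51, random lists -0.79 to 0.65). A culture round shared by the replicates numbered 1 also stays open: 0% of the caudal list were highest in replicate 1 of both RA groups (random median 14.3%), which by the prediction written before argues against it, and it was left open afterwards because all 3 genes of the pattern were.

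Sox17 and Foxa1 were higher in GFP+ cells under RA than in both other groups. Since Foxa2 is also a gene of endoderm, a sort on its reporter would not remove endoderm cells, and such cells among the GFP+ cells under RA are a candidate explanation. In 11 further gut endoderm genes the median log2 fold change was 1.35 (random lists -0.64 to 0.42), but 4 were higher (Tmprss2, Apob, Nepn and Dsp) and 2 lower (Elf3 and Rbm47), and camera did not place the list above other genes (adjusted p = 0.107, and adjusted p = 0.406 with an estimated correlation). Against GFP+ cells under SAG, 7 of the 11 were lower under SAG and 0 higher (camera adjusted p = 2.67e-07, and adjusted p = 0.0411 with an estimated correlation). The median met the bounds of the prediction written before. The explanation was left open afterwards because camera did not call the list under the sort and its members go both ways. A floor plate with endoderm genes could not be told apart from a mixed sort in bulk libraries.

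Stra8, Sohlh2, Rec8 and Ddx4 were far lower in GFP+ cells under SAG than under RA, and a loss of germline and meiosis genes as a set was tested on 17 others. Their median was -2.73 (random lists -0.77 to 0.49), with 13 lower and 0 higher (camera adjusted p = 3.36e-09, and adjusted p = 0.0712 with an estimated correlation). The median is the same with Sycp1, which had 0 counts under SAG, at its bound. The naive pluripotency list moved with it, with 7 lower and 2 higher of 14 and a median of -0.90 (random lists -0.43 to 0.37; camera adjusted p = 0.00666, and adjusted p = 0.156 with an estimated correlation). Tdrd12 of the germline list fell from 47.8 CPM in GFP- to 7.04 CPM in GFP+ cells under RA and 1.85 CPM under SAG. Under the sort, 3 of the 17 germline genes were lower and 1, Tdrd1, higher, while 12 of the 14 naive genes were lower and 0 higher. Camera placed the germline list lower there (adjusted p = 0.0318, and adjusted p = 0.39 with an estimated correlation). Rec8 went the other way, at 36.7, 28.4 and 45.1 CPM in GFP- and 87, 94.5 and 93.4 CPM in GFP+ replicates 1 to 3, as did Ddx4. A response of the set and fewer cells that express both lists may each give the fall under SAG, and which holds was not tested.

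Col4a1 and Col4a2 were among the smallest p-values of the sort under RA, with Col4a1 at 53.3 CPM in GFP- and 492 CPM in GFP+ libraries. Basement membrane genes as a set were tested on 11 others, with a median of 0.75 (random lists -0.2 to 0.26) and 5 higher and 0 lower, Col18a1 from 531 to 1340 CPM and Lamb1 from 85.7 to 295 CPM among them (camera adjusted p = 5.42e-05, and adjusted p = 0.0776 with an estimated correlation). Under SAG 6 of the 11 were lower than in GFP+ cells under RA and 0 higher (camera adjusted p = 0.00485, and adjusted p = 0.156 with an estimated correlation). Markers of other cell types follow the same pattern over GFP- under RA, GFP+ under RA and GFP+ under SAG, such as Sox17 (1.33, 46.3 and 0.424 CPM), Osr1 (0.0607, 5.04 and 0 CPM) and the gut endoderm list (medians 1.35 and -3.67), so such cells may carry part of the change in the set, which was not tested.

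A rise of hindbrain visceral motor neuron genes as a set under SAG was tested on 6 genes, and the median was 0.31 (random lists -1.44 to 0.84), with 3 higher (Phox2a, Tbx20 and Slc18a3) and 3 lower (Tbx2, Tbx3 and Prph). By the prediction written before, a median under 0.5 argues against this, and it was left open afterwards because the members go both ways. H19 fell from 162 CPM under RA to 8.12 CPM under SAG in GFP+ cells, but a loss of imprinted genes as a set is argued against: in 17 others the median was 0.25 (random lists -0.16 to 0.21), with 6 higher and 3 lower. These members go both ways too, but their median lay above the random range, opposite to a loss. Camera did not call the list (adjusted p = 0.488, and adjusted p = 0.499 with an estimated correlation).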
